A study of Homo sapiens with 12 samples.

How the data were processed

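The processed data were a single table of RPKM values (reads scaled by gene length and by the number of reads in the library), 1 column per RNA library and 1 row per gene, deposited by the authors. Per the labels' protocols, total RNA was extracted with a column kit and Trizol, and libraries were made with the Illumina TruSeq RNAseq v2 kit, which selects polyadenylated RNA and does not mark the strand. Per the submitters' processing notes, the genome build was hg19 and the tools included Bowtie, MACS2, deepTools 2.2.3, STAR 2.5.1, Cufflinks 2.2.1 and DESeq2 1.1, with no role or order. Which of these made the RPKM values, the gene annotation, the treatment of reads that match several places and any filter are not given in the sources used here. A value per gene length makes the values of very short genes unstable, because a gene shorter than a sequenced fragment has almost no positions at which a fragment can start. RPKM also depends on the sum over all genes of a library, so that each value is relative to the rest of its library.

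Columns were matched to samples by the library number in the description label, and groups and replicate numbers were taken from the sample titles. The comparison was THZ1 against vehicle, 3 libraries against 3. Chromatin immunoprecipitation samples were not analysed here. Of 25365 gene rows, 6772 were listed at 0 in all 6 libraries. 28 gene names had been turned into dates, 2 of which each named 2 rows. They were kept as separate rows and none is named in the text. The names were looked up in RefSeq tables of assembly GRCh38.p14: 22531 were current names, 1530 were older symbols and 1304 were unmatched. That build differs from hg19, so no coordinates are given, and the tables served only for names, gene types and gene spans. Spans were found for 97.6% of the tested genes.

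Read depth was not given. In each other library, genes that stayed under 0.15 RPKM everywhere were compared with their values in THZ1 replicate 3, and 60.8% to 64.1% of 1116 to 1282 such genes had ratios that whole reads of 1 to 4 would give, within 0.02 on the log2 scale. The position of these ratios gives the relative depth: 0.672, 0.672 and 0.834 for vehicle replicates 1 to 3 and 0.954, 0.865 and 1 for THZ1 replicates 1 to 3. Absolute depth stays unknown, so no counting error is given. The median half-width of the 95% confidence interval of a log2 fold change was 0.22 among genes other than small RNAs.

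Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, group as the only term, two-sided) among genes with a mean of at least 1 RPKM over the 6 libraries. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. A size threshold of 1 on that scale was applied as a second count. 27 gene lists written from textbook knowledge were tested with limma camera at its preset inter-gene correlation of 0.01, adjusted over the lists with at least 3 tested members, and with camera at an estimated correlation and fry beside it. The lists cover estrogen receptor targets, estrogen-repressed genes, luminal lineage transcription factors, transcription kinases and TFIIH, P-TEFb release and elongation factors, immediate-early genes, E2F targets and DNA replication, mitosis and G2/M, homologous recombination and Fanconi genes, p53 targets, the BCL2 family, ATF4 and unfolded protein response, NRF2 targets, heat shock response, cholesterol biosynthesis, interferon-stimulated genes, NF-kB targets, hypoxia and glycolysis, replication-dependent histones, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, epithelial and luminal keratins and junctions, and markers of basal epithelial, fibroblast, immune and endothelial cells.

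Genes named in the report follow a rule: 12 fixed genes (ESR1, CDK7, CCNH, MNAT1, CDK9, CDK12, CDK13, TFF1, PGR, GREB1, MYC and CCND1), up to 10 rising and 10 falling genes with the largest fold change among those that passed with a mean of at least 5 RPKM and no overlap between arms, and per list up to 4 members that passed or, if none did, the 2 of smallest p. Genes named only in the closing observations were chosen after their values were seen. Small RNA genes (microRNA, small nucleolar, small nuclear and similar genes, 234 of the 11790 tested) were recognised by RefSeq gene type or by name.

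The tests of THZ1 against vehicle were tried on simulated data: log2 values were drawn for the tested genes with their means and within-group SDs, 200 genes per run were changed by 0.5, 1, 2 or 3 on the log2 scale, and 20 runs were made. With all 11790 genes, 48.3%, 88.6%, 97.1% and 98.1% of them were recovered, with 7.40 false calls per run. A list shifted by 0.2 was found in 100% of runs. Each gene was drawn independently, so the runs held no differences shared by many genes of a library, such as a trend along gene span. The share of genes recovered also depends on the 200 genes changed, since fewer changed genes make the adjusted threshold stricter.

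The lists, the rule for named genes, the tests and a set of alternatives were chosen before the data were examined. These alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, a filter at 5 RPKM, median ratio scaling, quantile normalization, eBayes without a trend and with robust estimation, the replicate number as a block, each library left out in turn, rows of 1 symbol averaged, and for lists the estimated correlation and fry. Added after seeing the data were runs without small RNA genes, without these and vehicle replicate 2, with the trend along gene span removed from each library (by lowess with a span of 0.3), and with the library number series (59 to 61 against 65 to 67) as a block. Figures were drawn with matplotlib 3.10.9.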

Results

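RNA was sequenced from MCF7 cells, an estrogen receptor (ER) positive human breast cancer line, that expressed the Y537S form of ER from a doxycycline-inducible construct. Y537S is a substitution in the ligand-binding domain of ER, the product of ESR1, that keeps the receptor active without estrogen and is known from endocrine-resistant metastatic disease. The cells were kept in hormone-deprived medium with doxycycline and received either the solvent (DMSO) or THZ1 for 24 h. THZ1 is a covalent inhibitor of CDK7, the kinase subunit of the CDK-activating complex and of the transcription factor TFIIH, and it also binds CDK12 and CDK13. The labels write its dose as 10nm, read here as 10 nM. Each arm held 3 libraries. The series also held 6 H3K27ac chromatin immunoprecipitation samples, 3 with wild-type ER and estradiol and 3 with induced Y537S ER, which were not analysed here. The series description also mentions treatment for 6 h, but the series held no such sample.

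Expression was given as RPKM for 25365 gene rows per library. Between 11585 and 11716 genes per library stood at 1 RPKM or more, and 11790 genes with a mean of at least 1 RPKM over the 6 libraries were tested. Read totals were not given. Steps between the lowest values put the read depth of the other libraries at 0.672 to 0.954 of that of THZ1 replicate 3, with vehicle replicates 1 and 2 the shallowest. Every vehicle library (0.834 at most) was shallower than every THZ1 library (0.865 at least). Depth and treatment therefore cannot be told apart. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

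The comparison of THZ1 with vehicle asked which transcripts respond to inhibition of CDK7 in cells that express a constitutively active ER. No protein-coding transcript passed the test after 24 h. The 3 genes that did were small RNAs: the microRNA gene MIR621 and the small nucleolar RNA gene SNORA29 rose, and the small nucleolar RNA gene SNORA76A fell. Transcripts of ESR1, of the kinases THZ1 binds and of the estrogen-induced genes TFF1, PGR and GREB1 differed between the arms by less than the test could separate from the spread between replicates. RPKM is relative to the rest of each library, so a fall or rise shared by most transcripts would not show here. Among the 11556 tested genes other than small RNAs, 11437 had a 95% confidence interval wholly within a 2-fold change of RPKM + 1. For 10676 it lay within a 1.5-fold change of RPKM + 1. The fold change of RPKM itself can be larger for low genes, so these counts do not bound it.

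ESR1 was measured at 69.2 ± 16.7 RPKM in vehicle and 79.4 ± 3.19 RPKM in THZ1 libraries (mean ± SD, n = 3 per group here and below), a log2 fold change of 0.22 (95% interval -0.18 to 0.63, adjusted p = 0.674). The 3 vehicle values were 72.8, 51.0 and 83.9 RPKM and the 3 THZ1 values 79.4, 82.6 and 76.2 RPKM, so that vehicle replicate 2 stood apart, and without it the log2 fold change was 0.022. A value per gene does not tell transcripts of the cells' own ESR1 from those of the construct. CDK7, the main target of THZ1, stood at 27.8 ± 3.65 RPKM in vehicle and 26.5 ± 0.827 RPKM in THZ1 libraries (log2 fold change -0.059, interval -0.29 to 0.18, adjusted p = 0.825, and 0.0055 without vehicle replicate 2). Its partners CCNH, the cyclin of the complex, and MNAT1, the assembly factor, had log2 fold changes of -0.025 (interval -0.17 to 0.12, with the sign turned under quantile normalization) and 0.0056 (interval -0.31 to 0.32), or -0.0010 and 0.070 without vehicle replicate 2. CDK9, the kinase of the elongation factor P-TEFb, was at 31.4 ± 2.06 RPKM in vehicle and 29.95 ± 1.1004 RPKM in THZ1 libraries, a log2 fold change of -0.063 with an interval of -0.22 to 0.097, and -0.017 without that library. CDK12 and CDK13, which phosphorylate RNA polymerase II during elongation, had log2 fold changes of 0.14 and 0.12, and without vehicle replicate 2 these were -0.0048 and 0.012. As each library was left out in turn, the log2 fold change ran from 0.022 to 0.38 for ESR1, -0.17 to 0.0055 for CDK7, -0.059 to 0.0057 for CCNH, -0.12 to 0.11 for MNAT1 and -0.11 to -0.017 for CDK9. For CDK12 and CDK13 it ran from -0.0048 to 0.22 and from 0.012 to 0.19. The extremes of ESR1, CDK7, CDK9, CDK12 and CDK13 came from the runs without vehicle replicates 2 and 3.

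TFF1, a classical estrogen-induced gene of breast cancer cells, was at 338 ± 22.2 RPKM in vehicle and 301 ± 35.9 RPKM in THZ1 libraries (log2 fold change -0.17, interval -0.42 to 0.080, adjusted p = 0.669). PGR, the progesterone receptor gene, was at 2.81 ± 0.653 and 3.27 ± 0.208 RPKM, and GREB1, an ER cofactor induced by estrogen, was at 71.6 ± 16.8 and 80.1 ± 1.88 RPKM. Both had their lowest value in vehicle replicate 2, and their log2 fold changes of 0.18 and 0.19 became 0.049 and 0.0095 without it. The MYC proto-oncogene was at 69.3 ± 1.32 RPKM in vehicle and 65.8 ± 3.36 RPKM in THZ1 libraries, with no overlap between the arms, at a log2 fold change of -0.075 that did not pass (adjusted p = 0.679). Such a lack of overlap was common: chance parts 10% of genes, and 15.1% of the 11556 genes other than small RNAs were parted here, 1116 lower and 624 higher. CCND1, which encodes cyclin D1, had a log2 fold change of -0.0016 (interval -0.17 to 0.17), whose sign turned under median ratio scaling and under quantile normalization and which was -0.030 without vehicle replicate 2. Leaving out single libraries gave log2 fold changes of -0.25 to -0.077 for TFF1, 0.049 to 0.30 for PGR, 0.0095 to 0.35 for GREB1, -0.098 to -0.033 for MYC and -0.054 to 0.043 for CCND1.

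**Figure D1:**
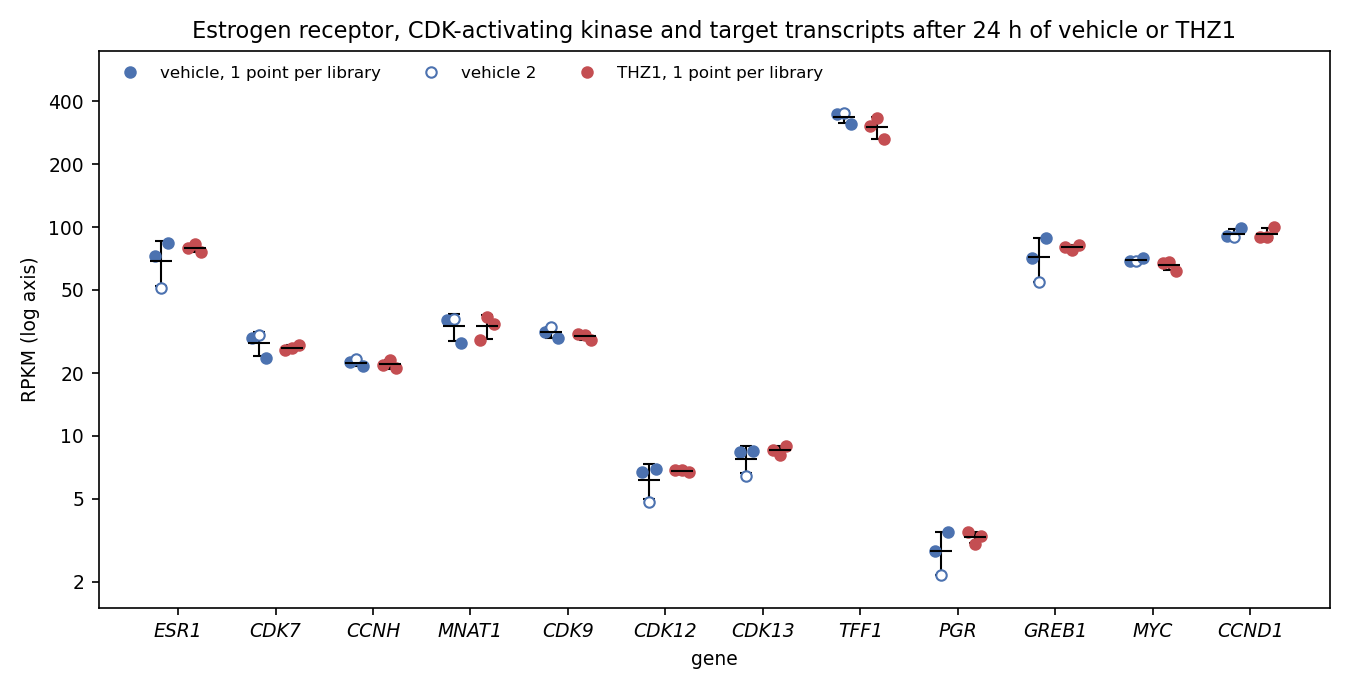
RPKM on a log axis of the 12 fixed genes, with 1 point per library for vehicle (blue; vehicle replicate 2 open) and THZ1 (red) and bars for the mean and SD of 3 libraries. The arms overlap for every gene shown except MYC, and vehicle replicate 2 is the lowest library for ESR1, CDK12, CDK13, PGR, GREB1 and CCND1, as at 51.0 RPKM for ESR1.

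The small RNA calls were separations between values at or near 0 and values well above it. MIR621 was listed at 8.80e-09, 8.02e-29 and 7.73e-58 RPKM in the vehicle libraries and at 209.9, 145 and 187 RPKM in the THZ1 libraries (limma adjusted p = 2.49e-06). SNORA29 was listed at 0 in all 3 vehicle libraries and at 8.23, 18.2 and 7.85 RPKM with THZ1 (adjusted p = 0.0252). SNORA76A was listed at 13.4, 13.4 and 21.5 RPKM in vehicle and at 0 in all 3 THZ1 libraries (adjusted p = 6.57e-04). Small nucleolar RNAs guide chemical modification of ribosomal RNA and are present in all cells, so a listed 0 is no proof of absence, and no fold is given against it. 130 of the 234 tested small RNA genes were listed below 0.01 RPKM in 1 vehicle library and at 5 RPKM or more in another, against 0 of the 11556 other genes.

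The limma test on log2(RPKM + 1) gave 3 calls at an adjusted p under 0.05, 2 higher and 1 lower, all of at least 2-fold, and 957 genes at an unadjusted p under 0.05 (589.5 by chance if genes were independent). Genes of a library vary together, and the other splits of the 6 libraries 3 against 3 gave 125 to 885 such genes. The excess over 589.5 is therefore no measure of an effect of THZ1. With single libraries left out, the unadjusted number ran from 416 without THZ1 replicate 1 to 1626 without vehicle replicate 3. With small RNA genes left out, the test gave 0 calls among 11556 genes and 1042 genes at an unadjusted p under 0.05, of which 880 were lower and 162 higher with THZ1. The split with vehicle replicates 1 and 2 and THZ1 replicate 3 on one side gave 1038 such genes. Leaving out vehicle replicate 1, 2 or 3 gave 5, 7 and 4 calls, and leaving out THZ1 replicate 1, 2 or 3 gave 7, 10 and 8. Each of these sets held MIR621, SNORA76A and other small RNAs, and the last also held PABPN1, named here after its value was seen, which encodes a poly(A) binding protein (log2 fold change -1.16, adjusted p = 0.0274). With small RNA genes and vehicle replicate 2 both left out there were 0 calls and 817 genes at an unadjusted p under 0.05. In simulated data with the spread of these libraries, the test recovered 88.6% of genes changed by 1 on the log2 scale and 48.3% of those changed by 0.5.

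Vehicle replicate 2 stood apart from the other libraries along gene span, the length of a gene from its first to its last exon. Its median deviation from the mean of the 6 libraries ran from 0.18 on the log2 scale in the decile of genes with the shortest spans (median 2.99 kb) to -0.19 in the decile with the longest (median 219.6 kb). The fold change of THZ1 against vehicle followed gene span in the opposite sense, from a median log2 fold change of -0.13 in the shortest to 0.090 in the longest decile. Without vehicle replicate 2 these medians were -0.086 and 0.016. Across 11272 genes, which are not independent replicates, Spearman's rho between fold change and span was 0.486, and 0.263 without vehicle replicate 2. Leaving out any other library gave 0.458 to 0.517.

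**Figure D2:**
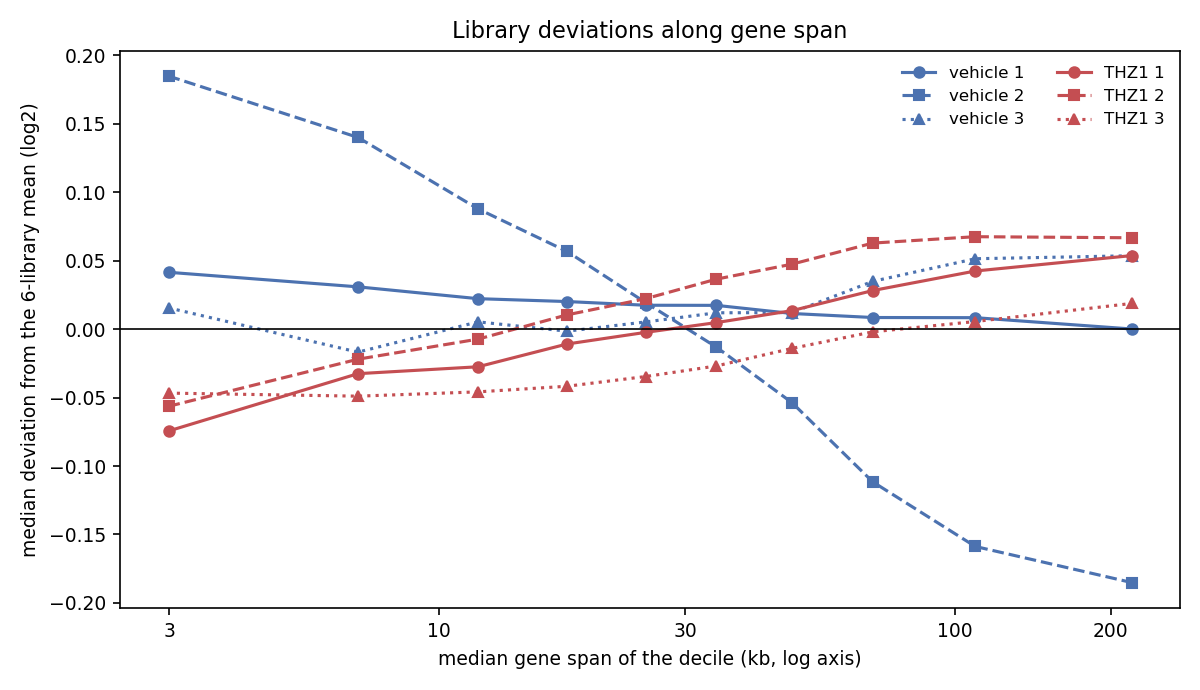
Median log2 deviation of each library from the mean of the 6 libraries (y axis) against the median span in kb of each decile of genes (x axis, log), with vehicle libraries in blue and THZ1 libraries in red. Vehicle replicate 2 runs from 0.18 to -0.19, while the other 5 libraries stay between -0.074 and 0.068.

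Of 27 gene lists, 24 had enough tested members for the camera test, and 5 passed, 2 higher and 3 lower with THZ1. The mitosis and G2/M list and the homologous recombination and Fanconi genes list were higher. The lists of cytosolic ribosomal proteins, of nuclear-encoded oxidative phosphorylation and of immediate-early genes were lower. None of these 5 calls held when the correlation between genes was estimated, with adjusted p of 0.841 to 0.942 over all lists, and fry called 0 lists as moving one way (lowest adjusted p = 0.423). No member of any list passed over all genes tested. Adjusted over the list alone, HIST1H3H of the histones and BCL3 of the NF-kB targets passed, both lower. That adjustment was made within each list and not across the 27 lists, so some such passes can arise by chance.

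The mitosis and G2/M list was higher at the preset correlation only: 33 of 45 tested members had a fold change above 0 (36 under quantile normalization), the median log2 fold change was 0.060 and the camera adjusted p was 9.47e-04 (adjusted p = 0.841 with an estimated correlation). By library, the median deviation of its members was 0.0090, 0.0012 and -0.071 in vehicle replicates 1 to 3. In THZ1 replicates 1 to 3 it was 0.038, 0.059 and 0.0037, so vehicle replicate 1 lay above THZ1 replicate 3. KIF23 at 26.6 ± 0.458 RPKM in vehicle and 30.7 ± 1.45 in THZ1 libraries (log2 fold change 0.20, adjusted p = 0.587), a kinesin of the cytokinetic midzone, and KIF18A, a kinesin of chromosome alignment, at 5.55 ± 0.103 and 6.44 ± 0.158 RPKM had the smallest p and did not pass singly. Without vehicle replicate 2 the median was 0.080 and the adjusted p 2.12e-06. The call was lost without vehicle replicate 3 (median 0.027, adjusted p = 0.226), and over 23 alternatives the adjusted p ranged from 3.56e-07 to 0.841. In the homologous recombination and Fanconi genes list, 22 of 34 members were above 0 (25 under quantile normalization) with a median of 0.090 (adjusted p = 0.00378, and adjusted p = 0.841 with an estimated correlation). Its members of smallest p, the damage checkpoint kinase ATR at 5.26 ± 0.682 RPKM in vehicle and 6.37 ± 0.160 in THZ1 libraries (log2 fold change 0.24, or 0.15 without vehicle replicate 2) and the nuclease gene MRE11A at 5.25 ± 0.493 and 6.04 ± 0.145 RPKM, did not pass. Without vehicle replicate 2 the median was 0.066 (adjusted p = 0.001005) and the call was lost without vehicle replicate 3 (adjusted p = 0.0621) and, for genes of a median span of 69.1 kb, with the gene span trend removed (median 0.033, adjusted p = 0.289), but not with that trend removed and vehicle replicate 2 left out (median 0.057, adjusted p = 0.0309). The range over 23 alternatives was 0.001005 to 0.841.

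Other cell cycle groups did not pass. In the E2F targets and DNA replication list 25 of 43 members were below 0 (median -0.033, adjusted p = 0.682). The median ran from -0.072 without vehicle replicate 3 to 0.011 without vehicle replicate 2 and was 0.0067, with 19 members below 0, under quantile normalization. The replication licensing factor CDT1 was at 30.4 ± 2.25 RPKM in vehicle and 22.6 ± 2.02 in THZ1 libraries (log2 fold change -0.41, adjusted p = 0.587). POLD1, the catalytic subunit of DNA polymerase delta, had a log2 fold change of -0.32. The replication-dependent histones list had 14 of 19 members below 0 (15 under quantile normalization), a median of -0.080 and an adjusted p of 0.0505, and it passed without vehicle replicate 2 (median -0.16, adjusted p = 3.53e-04), without THZ1 replicate 2 (median -0.17, adjusted p = 0.0328) and without THZ1 replicate 3 (median -0.13, adjusted p = 0.0125). It also passed with a pseudocount of 0.1 (0.0490), no filter (0.0324), the filter at 5 RPKM (median -0.15, adjusted p = 0.0152), median ratio scaling (0.0359), the replicate block (0.0371) and small RNA genes left out (0.0273). It did not pass without vehicle replicate 1 (0.0890), without vehicle replicate 3 (median -0.041, adjusted p = 0.315) or without THZ1 replicate 1 (0.211), and its direction turned with the gene span trend removed (median 0.078, adjusted p = 0.916). The list passed in 10 of 23 alternatives, and its adjusted p ranged from 3.66e-05 to 0.916 over all of them. Fry in its form for change in either direction gave this list an adjusted p of 1.80e-04, the only one of the 24 to pass. HIST1H3H was at 18.7 ± 1.09 RPKM in vehicle and 12.0 ± 0.936 RPKM in THZ1 libraries, a log2 fold change of -0.60 (adjusted p = 0.334 over all genes and 0.00215 over the list alone). HIST2H2AA3, which has a near-identical copy so that its value is uncertain, had a log2 fold change of -0.41. The library kit selects polyadenylated RNA. How far it captured replication-dependent histone transcripts, and whether evenly between libraries, is not known, so these values are no sure measure of their levels.

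The cytosolic ribosomal proteins list, at a median of 1074 RPKM in vehicle, had all 75 tested members below 0 (50 under quantile normalization) with a median log2 fold change of -0.12 (camera adjusted p = 2.03e-05, and adjusted p = 0.878 with an estimated correlation). By library, the median deviation of its members from the mean of the 6 libraries was 0.066, 0.26 and -0.14 in vehicle replicates 1 to 3. In THZ1 replicates 1 to 3 it was -0.11, -0.0023 and -0.060, so vehicle replicate 3 lay below every THZ1 library. Its genes have short spans, with a median of 5.01 kb. Without vehicle replicate 2 the median was -0.026, 25 members lay above 0 and the call was lost (adjusted p = 0.723), and without vehicle replicate 3 the median was -0.22. The call was also lost under quantile normalization (median -0.018, adjusted p = 0.0741) and with the gene span trend removed (median -0.014, adjusted p = 0.471), and the adjusted p ranged from 5.85e-15 to 0.878 over 23 alternatives. RPS15, at 941 ± 107 RPKM in vehicle and 686 ± 109.8 in THZ1 libraries, and RPS29, at 2271 ± 265 and 1854 ± 113, had the smallest p, and neither passed (adjusted p = 0.587 and 0.614). The nuclear-encoded oxidative phosphorylation list, which covers subunits of the respiratory chain and ATP synthase, had 52 of 55 members below 0 (43 under quantile normalization) and a median of -0.11 (adjusted p = 1.80e-06, and adjusted p = 0.841 with an estimated correlation). Without vehicle replicate 2 the median was -0.050 and the adjusted p 0.0217, and without vehicle replicate 3 the median was -0.19. The median was -0.047 with the gene span trend removed (adjusted p = 0.00647), and the call was lost with vehicle replicate 2 left out as well (median -0.0084, adjusted p = 0.563). The range over 23 alternatives was 9.11e-13 to 0.841. The complex I subunit NDUFS7 was at 36.7 ± 3.81 and 24.2 ± 4.88 RPKM (log2 fold change -0.60, adjusted p = 0.587), and NDUFB7 of the same complex had a log2 fold change of -0.25. The list of mitochondrially encoded transcripts was not analysed here.

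Genes of the transcription machinery did not pass as groups, and immediate-early genes were lower at the preset correlation. In the transcription kinases and TFIIH list, 12 of 20 members were above 0 (median 0.043, adjusted p = 0.163), and 15 under quantile normalization (median 0.078). The median ran from 0.0037 without vehicle replicate 2 to 0.081 without THZ1 replicate 1. Cyclin genes CCNC, of the Mediator kinase module, and CCNT2, of P-TEFb, had log2 fold changes of 0.11 and 0.17 (0.12 and 0.070 without vehicle replicate 2). The P-TEFb release and elongation factors list had a median of -0.051 over 13 members (adjusted p = 0.682), and of -0.0013 under quantile normalization. It ran from -0.075 without THZ1 replicate 2 to -0.022 without vehicle replicate 1, and was -0.026 without vehicle replicate 2. Among its members were NELFA, of the negative elongation factor, at -0.21 and the P-TEFb inhibitor gene HEXIM2 at -0.14 (-0.20 to -0.080 for HEXIM2 with single libraries left out). The list of immediate-early genes, whose products respond to growth signals with short-lived messages, had 26 of 35 members below 0 (23 under quantile normalization) and a median of -0.073 (adjusted p = 0.0122, and adjusted p = 0.841 with an estimated correlation). Without vehicle replicate 2 the median was -0.098 (adjusted p = 3.53e-04), and the call was lost without vehicle replicate 3 (median -0.042, adjusted p = 0.310), without THZ1 replicate 2 (adjusted p = 0.163) and under quantile normalization (adjusted p = 0.0550). With the gene span trend removed the direction turned (median 0.033, adjusted p = 0.954), and with vehicle replicate 2 left out as well the list did not pass (median -0.038, adjusted p = 0.113). Without THZ1 replicate 3 its median was -0.033, and the adjusted p ranged from 1.30e-04 to 0.954 over 23 alternatives. ID3, an inhibitor of DNA binding, was at 75.2 ± 4.004 RPKM in vehicle and 60.4 ± 2.66 RPKM with THZ1 (log2 fold change -0.31, adjusted p = 0.587), and the stress-responsive gene GADD45B was at 24.8 ± 0.940 and 20.4 ± 1.52 RPKM.

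Genes under the control of ER did not pass as a group. Of the estrogen receptor targets, 27 were above 0 and 25 below 0 (median 0.0087, adjusted p = 0.523), and under quantile normalization 35 were above and 17 below 0 (median 0.049). The median was -0.0071 without vehicle replicate 2 and ran from -0.017 without vehicle replicate 1 to 0.044 without THZ1 replicate 2. The 52 tested members spanned log2 fold changes from -0.35 to 0.29. CTSD, which encodes the lysosomal protease cathepsin D, was at 186 ± 11.9 RPKM in vehicle and 159 ± 5.07 RPKM in THZ1 libraries (log2 fold change -0.22, adjusted p = 0.587), and the secreted trefoil factor gene TFF3 was at 2.74 ± 0.650 and 1.90 ± 0.268 RPKM. The estrogen-repressed genes had a median of 0.027 over 14 members but a mean of -0.0068 (adjusted p = 0.682, in the upward direction). Their median ran from 0.015 without THZ1 replicate 1 to 0.051 without vehicle replicate 3, with 0.046 under quantile normalization. YPEL3 and IGFBP5, a binding protein of insulin-like growth factors, had log2 fold changes of -0.26 and 0.18 within it, or -0.16 and 0.10 without vehicle replicate 2. The luminal lineage transcription factors had 9 members above and 9 below 0 (median 0.017, adjusted p = 0.599), and 14 above and 4 below 0 under quantile normalization (median 0.048). Their median was -0.016 without vehicle replicate 2 and ran from -0.017 without THZ1 replicate 1 to 0.045 without vehicle replicate 3. SPDEF and GRHL1, both epithelial transcription factors, had log2 fold changes of -0.20 and 0.14. With single libraries left out the values were -0.48 to -0.23 for TFF3, -0.35 to -0.16 for YPEL3 and 0.10 to 0.23 for IGFBP5.

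Survival and stress groups did not pass either. In the BCL2 family, which governs mitochondrial apoptosis, 11 of 13 members were below 0 (median -0.070, adjusted p = 0.0716). The list passed without vehicle replicate 1 (median -0.13, adjusted p = 0.0301) and without THZ1 replicate 1 (median -0.12, adjusted p = 0.0419). Its median was -0.045 without THZ1 replicate 3, and the adjusted p lay within a range of 0.0301 to 0.841 over 23 alternatives. Its pro-apoptotic members BAD and BID were at 23.6 ± 2.73 and 23.4 ± 0.877 RPKM in vehicle and 17.3 ± 2.39 and 20.1 ± 1.23 RPKM in THZ1 libraries (log2 fold changes -0.43 and -0.21). The p53 targets had a median of 0.011 and a mean of -0.023, with camera pointing down (adjusted p = 0.873). Medians ran from -0.011 without vehicle replicate 2 to 0.022 without THZ1 replicate 3 (0.0028 under quantile normalization). FDXR, a mitochondrial reductase, and NINJ1 had log2 fold changes of -0.31 and -0.20. In the ATF4 and unfolded protein response list 22 of 29 members were below 0 (median -0.052, adjusted p = 0.192), but 15 under quantile normalization (median -0.0053). The median ran from -0.092 without vehicle replicate 3 to -0.026 without vehicle replicate 2. The stress transcription factors CEBPB and DDIT3 were at -0.43 and -0.20 (-0.47 and -0.12 without vehicle replicate 2). The NF-kB targets had 8 of 10 members below 0 (median -0.079, adjusted p = 0.199), and 7 under quantile normalization (median -0.046). Leaving out 1 library gave medians from -0.11 without vehicle replicate 3 to -0.051 without THZ1 replicate 3. Among them BCL3, a nuclear cofactor of NF-kB, was at 22.2 ± 1.76 RPKM in vehicle and 17.3 ± 0.906 RPKM in THZ1 libraries (adjusted p = 0.587 over all genes and 0.0301 over the list alone), and IRF1 had a log2 fold change of -0.19.

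The interferon-stimulated genes list, the antiviral program, had a median of -0.043 over 19 members (adjusted p = 0.811), from -0.092 without THZ1 replicate 1 to -0.0062 without vehicle replicate 2, and of -0.028 under quantile normalization. ISG15 was at -0.41 and IRF7 at -0.35 (-0.49 to -0.18 for IRF7 with single libraries left out, the extremes without THZ1 replicates 3 and 2). NRF2 targets, the antioxidant program, had a median of -0.069 over 20 members (adjusted p = 0.377), from -0.11 without vehicle replicate 3 to -0.024 without THZ1 replicate 3. It was -0.028 without vehicle replicate 2 and -0.0040 under quantile normalization. The ferritin gene FTH1 was at 627 ± 71.6 and 536.8 ± 17.4 RPKM (log2 fold change -0.22, or -0.13 without vehicle replicate 2) and G6PD had a log2 fold change of -0.13. The heat shock response list had a median of 0.0017 but a mean of -0.019, camera pointed down (adjusted p = 0.873), and the direction turned under quantile normalization (median 0.077). Its median ran from -0.058 without vehicle replicate 3 to 0.043 without vehicle replicate 2. HSPB1, a small heat shock protein, was at 2853 ± 446 RPKM in vehicle and 2188 ± 285 RPKM with THZ1 (log2 fold change -0.38, adjusted p = 0.608), and the cochaperone gene DNAJB1 had a log2 fold change of -0.13. The cholesterol biosynthesis list had a median of -0.024 over 22 members (adjusted p = 0.740), 0.028 under quantile normalization and from -0.063 without THZ1 replicate 2 to 0.040 without THZ1 replicate 3. MVD and MVK of the mevalonate pathway were at -0.33 and -0.17 (-0.22 and -0.11 without vehicle replicate 2). The hypoxia and glycolysis list had a median of -0.030 over 28 members (adjusted p = 0.761), 0.0095 under quantile normalization and from -0.045 without THZ1 replicate 2 to 0.027 without THZ1 replicate 3. The glycolytic genes PFKP and PGAM1 were at -0.15 and -0.10 (-0.13 to -0.067 for PGAM1 with single libraries left out).

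Markers of cell identity did not pass as groups. The list of epithelial and luminal keratins and junctions had a median of -0.12 over 16 members (adjusted p = 0.262), from -0.16 without vehicle replicate 3 to -0.025 without vehicle replicate 2, and of -0.018 under quantile normalization. The claudin gene CLDN4 was at 294 ± 14.0 and 253 ± 19.3 RPKM and the junction gene TJP3 at a log2 fold change of -0.22 (-0.30 to -0.14 for TJP3 with single libraries left out). The basal epithelial markers had 8 tested members and a median of 0.053 (adjusted p = 0.523), from -0.010 without vehicle replicate 1 to 0.092 without vehicle replicate 2, and of 0.045 under quantile normalization. CD44 was at 15.1 ± 0.463 and 17.4 ± 1.42 RPKM and the integrin gene ITGA6 at a log2 fold change of 0.17, or 0.083 without vehicle replicate 2. Of the fibroblast and mesenchymal markers, 6 of 21 were tested (median -0.0065, adjusted p = 0.811), and their median was 0.0034 under median ratio scaling, -0.028 under quantile normalization and from -0.059 without THZ1 replicate 3 to 0.048 without THZ1 replicate 2. The collagen genes COL6A1 and COL6A2 were at 4.13 ± 0.377 and 5.80 ± 0.230 RPKM in vehicle and 3.65 ± 0.518 and 5.29 ± 0.994 RPKM with THZ1 (log2 fold changes -0.14 and -0.12). Leaving out single libraries gave -0.23 to -0.073 for COL6A1 and -0.25 to -0.055 for COL6A2, lowest without THZ1 replicate 3 and highest without THZ1 replicate 2. 1 of 20 immune cell markers (CORO1A, log2 fold change -0.15, or -0.063 without vehicle replicate 2 and -0.24 without vehicle replicate 3) and 2 of 12 endothelial markers (VWF and ESAM, at 1.54 ± 0.257 and 0.990 ± 0.0883 RPKM in vehicle, with log2 fold changes of 0.063 and 0.025, or -0.023 and 0.056 without vehicle replicate 2, and -0.023 to 0.12 for VWF and -0.014 to 0.056 for ESAM over the runs that left out 1 library) reached the test, too few for camera.

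**Figure D3:**
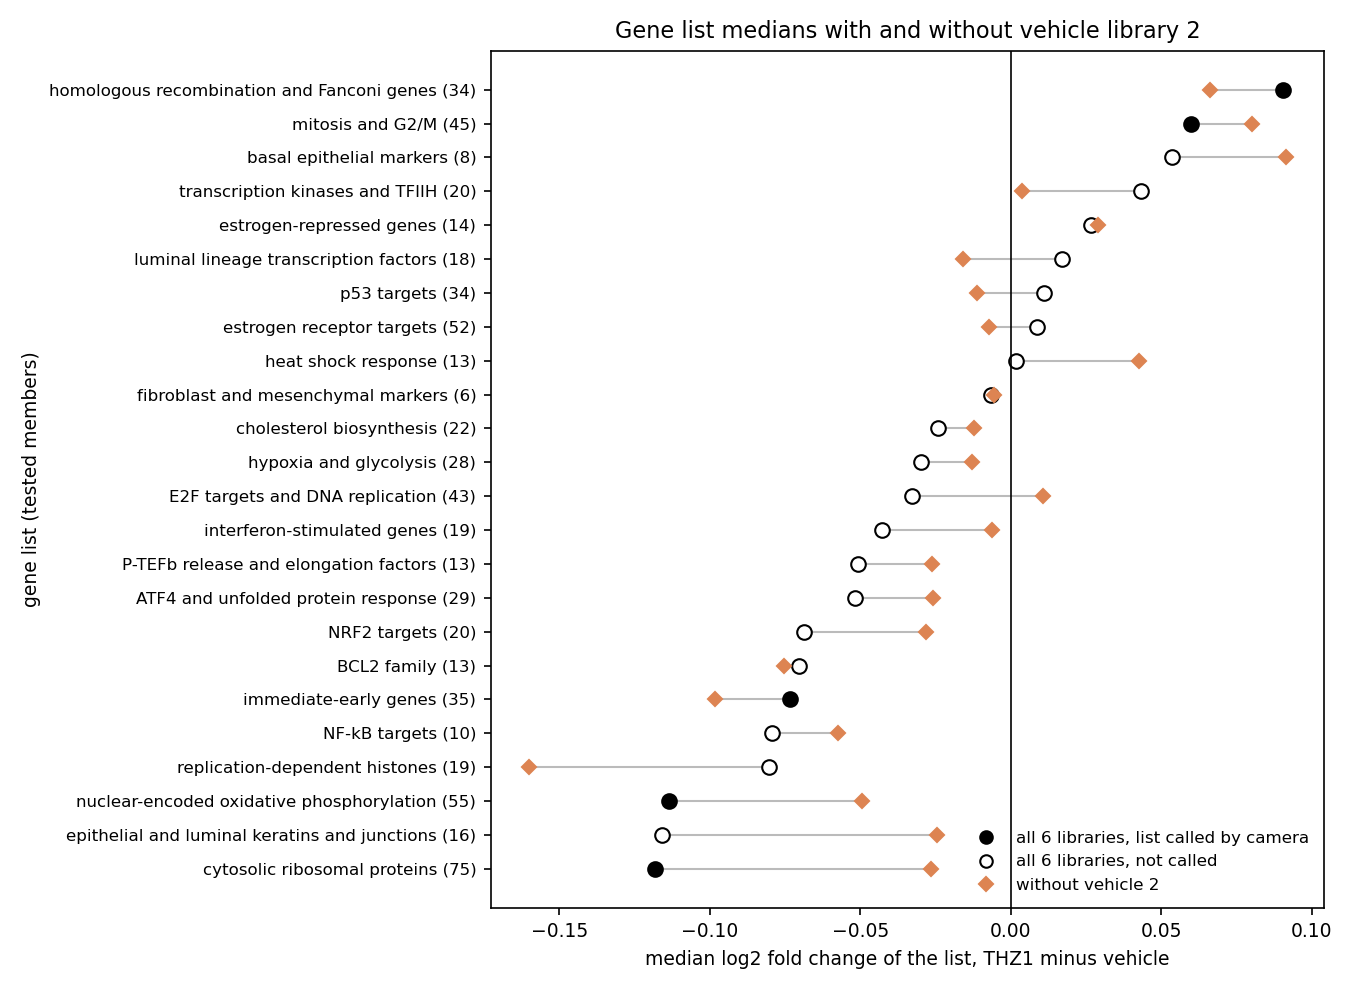
Median log2 fold change of THZ1 against vehicle (x axis) for the 24 gene lists tested (y axis, tested members in brackets), with all 6 libraries (circles, filled where camera passed at its preset correlation) and without vehicle replicate 2 (diamonds). The ribosomal protein median moves from -0.12 to -0.026 and the mitosis median from 0.060 to 0.080.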

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

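The runs without small RNA genes, with the gene span trend removed and with the library number series as a block were chosen after the results were seen, and the other alternatives were planned. Over all alternatives, 1326 of 1365 values of the 66 named genes kept their direction and their side of the threshold, as did 478 of 551 list results. For the genes this is a weak check, since 63 of them had not passed to begin with. Some alternatives, such as eBayes without a trend or with robust estimation, also leave every log2 fold change as it was. 24 list calls were lost, 2 of them with a turned direction, 12 were gained, and 39 list results turned direction in all. MIR621 and SNORA76A passed in every alternative that kept small RNA genes, and SNORA29 lost its call in 8. Leaving out 1 library moved the log2 fold change of 30 named genes by over 1.5 times in at least 1 run and turned that of 7. None of the 63 other named genes passed under any alternative (lowest limma adjusted p = 0.0921, HIST1H3H). Of the turned results, the immediate-early gene and ribosomal protein lists had been called, and the others had not passed before. Where a cause is not named below, the cause was not tested. Depth was known only relative to the deepest library, so the part of the spread that comes from counting was not separated.

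Without small RNA genes limma gave 0 calls (1042 genes at an unadjusted p under 0.05), none at least 2-fold (0), since the genes called were themselves left out. The count was likewise 0 without vehicle replicate 2 as well (817 unadjusted), 0 with the span trend removed (838) and 0 with both (633), and 0 at least 2-fold in each. Leaving out each library in turn gave 4 to 10 calls and 4 to 10 of at least 2-fold, with MIR621 and SNORA76A among each set. The other calls of the 2 smallest sets, named after their values were seen, were MIR3653, SNORD45A and SCARNA8 without vehicle replicate 1 and SNORA28 and SNORD60 without vehicle replicate 3. With no filter on low values, ZNF625-ZNF20, a readthrough of zinc finger genes named after its value was seen, was called beside MIR621 and SNORA76A (log2 fold change -0.47, adjusted p = 0.00592). The replicate block gave 2 calls, 1 higher and 1 lower (788 unadjusted), and 6 lists. Deviations of equally numbered samples from their group means correlated at -0.11, -0.052, 0.0097, so the numbers were not taken to pair samples. Without small RNA genes these were 0.045, -0.17 and -0.056. Unequally numbered samples then ranged from -0.26 (vehicle replicate 1 with THZ1 replicate 3) to 0.28 (vehicle replicate 1 with THZ1 replicate 2). The library number block gave 3 calls (2004 unadjusted). Numbers 59 to 61 held vehicle replicates 1 and 3 and THZ1 replicate 2. Numbers 65 to 67 held vehicle replicate 2 and THZ1 replicates 1 and 3, so arm and number series are partly confounded.

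Camera called 0 lists with an estimated correlation, fry 0, quantile normalization 3, removal of the span trend 2, the same without vehicle replicate 2 also 2, and leaving out each library 2 to 6. The mean correlation between replicates, 0.955 as reported, was 0.922 and 0.946 with pseudocounts of 0.1 and 0.5, 0.979 with no filter, 0.926 with the filter at 5 RPKM, 0.993 without small RNA genes, 0.995 without vehicle replicate 2 as well, 0.994 with the trend removed and 0.995 with both. The rise without small RNA genes follows from their spread, a median within-group SD of 2.29 on the log2 scale against 0.11 for other genes.

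Turned direction, with the adjusted p of lists and the log2 fold change of genes under the alternative, none of them passing: with no filter, fibroblast and mesenchymal markers (0.941). With the filter at 5 RPKM, P-TEFb release and elongation factors (0.894) and heat shock response (0.894), with fewer members tested. Under median ratio scaling, CCND1 (0.00998). Under quantile normalization, E2F targets and DNA replication (0.922), heat shock response (0.540), cholesterol biosynthesis (0.666), hypoxia and glycolysis (0.889), CCNH (0.027) and CCND1 (0.065). Without small RNA genes and vehicle replicate 2, luminal lineage transcription factors (0.848), E2F targets and DNA replication (0.506), heat shock response (0.712), interferon-stimulated genes (0.964), hypoxia and glycolysis (0.802), fibroblast and mesenchymal markers (0.848), CDK7 (0.0055), CDK12 (-0.0048) and VWF (-0.023). With the span trend removed, immediate-early genes (0.954), p53 targets (0.849), heat shock response (0.780), interferon-stimulated genes (0.780), replication-dependent histones (0.916), MNAT1 (-0.078), CDK9 (0.043), MYC (0.0088), CCND1 (0.055) and VWF (-0.018). With both, luminal lineage transcription factors (0.937), E2F targets and DNA replication (0.470), heat shock response (0.563), interferon-stimulated genes (0.701), hypoxia and glycolysis (0.872), cytosolic ribosomal proteins (0.342), fibroblast and mesenchymal markers (0.937), CDK7 (0.0088), CDK9 (0.043), CDK12 (-0.016), CDK13 (-5.0e-04), GREB1 (-0.0037), CCND1 (0.0035) and VWF (-0.037). With the library number block, p53 targets (0.968), cholesterol biosynthesis (0.965) and ESAM (-0.0012).

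Over the 6 runs that each left out 1 library, results that turned direction in at least 1 ranged as follows. Adjusted p: luminal lineage transcription factors 0.226 to 0.859, E2F targets and DNA replication 0.226 to 0.967, p53 targets 0.745 to 0.909, heat shock response 0.309 to 0.967, cholesterol biosynthesis 0.163 to 0.859, interferon-stimulated genes 0.613 to 0.967, hypoxia and glycolysis 0.334 to 0.850, fibroblast and mesenchymal markers 0.293 to 0.859. Log2 fold change: CDK7 -0.17 to 0.0055, CCNH -0.059 to 0.0057, MNAT1 -0.12 to 0.11, CDK12 -0.0048 to 0.22, CCND1 -0.054 to 0.043, VWF -0.023 to 0.12, ESAM -0.014 to 0.056.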

Other observations

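The tests on small RNA values and on gene span were chosen after the results were seen, the counts over splits of the libraries were planned, and the genes of the next paragraph were named after their values were seen.

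The antisense transcript HOXC-AS1 (2.67 ± 0.0807 RPKM in vehicle and 1.21 ± 0.209 RPKM in THZ1 libraries, log2 fold change -0.74, limma adjusted p = 0.388), HOXC11 (3.82 ± 0.470 RPKM in vehicle and 2.42 ± 0.252 RPKM in THZ1 libraries, log2 fold change -0.50) and HOXC13-AS (4.84 ± 0.358 RPKM in vehicle and 3.48 ± 0.215 RPKM in THZ1 libraries, log2 fold change -0.38) come from the HOXC cluster of homeodomain transcription factor genes and did not pass over all genes. After these were seen, the other tested HOX transcripts were looked up: all 8 of the cluster had a fold change below 0 as deposited, under median ratio scaling and under quantile normalization (adjusted p = 0.388 to 0.881), and so had 5 of 5 from HOXA and HOXB. As deposited, 51.4% of the tested genes other than small RNAs were below 0. With the span trend removed and vehicle replicate 2 left out, 6 of the 8 HOXC transcripts lay below 0, and 3 of the 5 from HOXA and HOXB lay above 0. Whether the cluster shifted as a group cannot be tested on the libraries from which its transcripts were picked. HBA1, an alpha globin gene, was at 8.57 ± 1.59 RPKM in vehicle and 4.44 ± 0.845 RPKM in THZ1 libraries, log2 fold change -0.82, and HBA2, a near-identical copy so that the share of each is uncertain, was at 5.69 ± 1.08 RPKM in vehicle and 3.11 ± 0.539 RPKM in THZ1 libraries, log2 fold change -0.70. PAM16, of the mitochondrial protein import motor, was at 45.3 ± 3.64 RPKM in vehicle and 27.3 ± 7.16 RPKM in THZ1 libraries, log2 fold change -0.74. The uncharacterised transcript LOC100996758 was at 1.41 ± 0.203 RPKM in vehicle and 3.40 ± 0.808 RPKM in THZ1 libraries, log2 fold change 0.85. None of these 4 passed (adjusted p = 0.587 for each). Among genes other than small RNAs KRT8, a keratin of luminal epithelium, was the most abundant at 5254 ± 466 RPKM in vehicle and 4796 ± 43.2 RPKM in THZ1 libraries, followed by GAPDH.

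The calls for MIR621, SNORA29 and SNORA76A may come from the instability of values of genes shorter than a sequenced fragment. Of the 234 tested small RNA genes 55.6% were below 0.01 RPKM in 1 vehicle library and at least 5 RPKM in another, against 0 of 11556 other genes (Fisher's exact p = 2.27e-241 over genes), and 114 did so among the THZ1 libraries, against 1 other gene, so this explanation had the values it needs. Of the 10 splits of the 6 libraries 3 against 3, 5 gave at least the 3 calls of the real one (highest other 4), and 5 at least its 3 calls of 2-fold or more (highest other 4). The real split thus did not stand out by its number of calls, and so few splits cannot give a share under 0.05 in any case. An effect of THZ1 on these RNAs stays open and was not tested, in libraries from a kit that selects polyadenylated RNA, which mature small nucleolar RNAs are not.

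The fold change followed gene span (rho = 0.486), and vehicle replicate 2 lay farthest from the other libraries along it. Without that library rho was 0.263, and among the other ways to part the remaining 5 libraries 3 against 2 the largest was 0.249, so that treatment, vehicle replicate 2 and differences between single libraries cannot be told apart with 10 partings. With the trend removed and vehicle replicate 2 left out, the fold of the ribosomal protein list went from -0.12 ± 0.093 (median ± SD over members) to 0.034 ± 0.095 (adjusted p = 0.342, 5.85e-15 to 0.878 over 23 alternatives). That of the oxidative phosphorylation list went from -0.11 ± 0.11 to -0.0084 ± 0.098 (adjusted p = 0.563, 9.11e-13 to 0.841 over 23). Both calls ended because the fold shrank. As deposited, vehicle replicate 2 had the highest median deviation for both lists (0.26 and 0.19), so leaving it out had to shrink a negative fold. Removing the trend would shrink these folds in the same way if THZ1 had caused the trend, so their loss does not tell the causes apart. The mitosis list kept its call, at 0.060 ± 0.12 before and 0.082 ± 0.068 after (adjusted p = 3.56e-07, 3.56e-07 to 0.841 over 23, 37 of 45 members above 0). Its median span of 29.4 kb lies between deciles with median log2 fold changes of -0.011 and 0.0018, so removing the trend could hardly have ended the call. After both steps its median deviation was -0.087 in vehicle replicate 3, -0.0057 in vehicle replicate 1 and 0.032 to 0.042 in THZ1 libraries. As deposited, vehicle replicate 1 (0.0090) lay above THZ1 replicate 3 (0.0037). The call was lost without vehicle replicate 3 (adjusted p = 0.226). For the number of called lists, 4 of the 10 splits gave at least the 5 of the real one, too few splits for a share under 0.05, and the highest other, 12 with vehicle replicates 1 and 2 and THZ1 replicate 2 on one side, points to a structure of the libraries across the arms, as does the split with vehicle replicates 1 and 2 and THZ1 replicate 3 on one side, with 1038 genes other than small RNAs at an unadjusted p under 0.05 against 1042 in the real one; THZ1 stays open as a cause, and GC content was not tested.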
